A study of Homo sapiens with 6 samples.

How the data were processed

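RNA on 6 arrays was compared, all from A549, a human lung cancer cell line. Cells had been transfected with a control siRNA, with MYEOV siRNA 1 or with MYEOV siRNA 2, with 2 arrays per group, and total RNA was taken 48 hours after transfection, per the labels' protocols. The RNA was amplified, converted to biotin-labelled cDNA and hybridised to Affymetrix whole-transcript arrays, which carry probes along the length of each transcript. The control siRNA's sequence and target, and the sequences of both MYEOV siRNAs, are not given in the sources used here. The labels do not say whether replicate arrays came from separate transfections, so the p-values measure the spread between these arrays, which may be technical.

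The deposited values are log2 signals made with RMA, per the submitters' processing notes, which name no version. RMA corrects background, equalises the distribution of values between arrays and summarises the probes of a transcript. It also compresses differences of dim transcripts, so fold changes near background are understated. The array medians lay between 4.08 and 4.10, and no further normalization was applied. The precision stated here is limited by the number of arrays and by not knowing what the replicates repeat.

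The deposited table holds 53617 rows. The platform annotation gave exactly 1 gene symbol to 16098 rows, several to 0 and none to 37519, which are unnamed here. The gene identifiers of all 16098 were found in the RefSeq gene table of assembly GRCh38.p14, and the rows stand for 14884 genes. For the 779 genes with more than 1 row, the row with the highest mean over all arrays was used. Genes were tested when their mean over the 6 arrays was at or above 5.45, the median of all named genes, which left 7442 genes.

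Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 6 arrays with 3 groups, which gives 3 residual degrees of freedom and 4.09 prior degrees of freedom. Contrasts were each siRNA against control, the mean of both siRNAs against control, and siRNA 1 against siRNA 2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. An exact permutation of 2 arrays against 2 cannot give a p below 0.333, so the calls rest on limma's sharing of spread between genes. Both siRNA comparisons use the same 2 control arrays. Their overlap and correlation were therefore set beside 100 simulations of unchanged groups against shared controls and beside the overlap of independent lists. The controls are too few to be split with 2 arrays on each side.

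Before the data were examined, 33 gene lists, the rule for named genes and most alternative settings were fixed. Of the 684 distinct genes in the lists, 402 had a named row. Camera with a preset correlation of 0.01 was run on the 28 lists with at least 3 tested members in 3 contrasts, and its p-values were adjusted over these 84 tests. A list's own members were also adjusted over the list alone. Named genes were MYEOV, the 10 largest changes per direction for each siRNA with both siRNA arrays beyond both control arrays, the 12 per direction with the largest smaller change among genes called by both siRNAs, and the 6 per direction that differed most between the siRNAs. Of each list, the members with the 4 largest mean changes per direction or called by both siRNAs could be named. Symbols of non-coding transcripts and unresolved open reading frames were left out of the ranking, which removed 17 called genes for siRNA 1 and 20 for siRNA 2. A gene named outside this rule is said to have been chosen after its values were seen.

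The fitting steps were tested on simulated data with the real genes' mean levels and with spreads drawn from limma's fitted prior. In each of 20 simulations over 7442 genes, 200 genes were changed. Of genes changed by 0.5 on the log2 scale, 65.9% were recovered for siRNA 1 against control, 64.6% for siRNA 2 and 80.6% for the mean of both. Of genes changed by 1 on that scale, 97.0%, 96.8% and 98.0% were recovered. False calls made up 4.79%, 5.20% and 5.19% of all calls. Camera called a list, G1/S and DNA replication, shifted by -0.3 on the log2 scale in 20 of 20 simulations. The simulated data follow the fitted model, with noise independent between genes, so these shares check the steps and not the real error rates. In the real data that list had an estimated correlation of 0.431.

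Alternatives were no filter or a filter at the 75th percentile, testing every row, averaging the rows of a gene, quantile normalization or median centring on top of RMA, fitting only the groups compared, the replicate number as a block, a variance prior with trend and robust estimation, array quality weights, each array left out in turn, camera with an estimated correlation, and fry. Gene lists without their most changed member and camera on the difference between the siRNAs were added after seeing the data. Figures were drawn with matplotlib 3.10.9. Scanner files were not used here.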

Results

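Gene expression was measured in A549 human lung cancer cells 48 hours after transfection of a control siRNA or of either of 2 siRNAs against MYEOV, a gene first described as overexpressed in myeloma. Each group had 2 arrays. The design asks which transcripts change when MYEOV is lowered, and using 2 siRNAs allows their effects to be compared. Values are log2 RMA signals, fold changes are given on the log2 scale with their standard error, and n = 2 arrays per group throughout.

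MYEOV, the targeted gene, was lower in all 4 arrays of the MYEOV siRNAs than in both control arrays. Its level was 6.20 and 6.50 in the control arrays, 5.34 and 5.19 with siRNA 1, and 5.23 and 4.70 with siRNA 2. The signal fell by 1.09 with siRNA 1 (95% confidence interval -1.50 to -0.67, limma, Benjamini-Hochberg adjusted p = 0.0215) and fell by 1.39 with siRNA 2 (interval -1.80 to -0.97, adjusted p = 0.00516). These changes correspond to a signal 52.9% and 61.7% lower than in the control. The siRNAs did not differ detectably in MYEOV, with a difference of 0.30 (interval -0.12 to 0.72, limma, Benjamini-Hochberg adjusted p = 0.370). For siRNA 1, the limma adjusted p of MYEOV was 0.135 with no filter, and 0.0671, 0.112, 0.0880 and 0.146 without control replicate 1, control replicate 2, siRNA 1 replicate 1 and siRNA 1 replicate 2. Over all alternatives it ran from 0.00825 to 0.146.

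**Figure D1:**
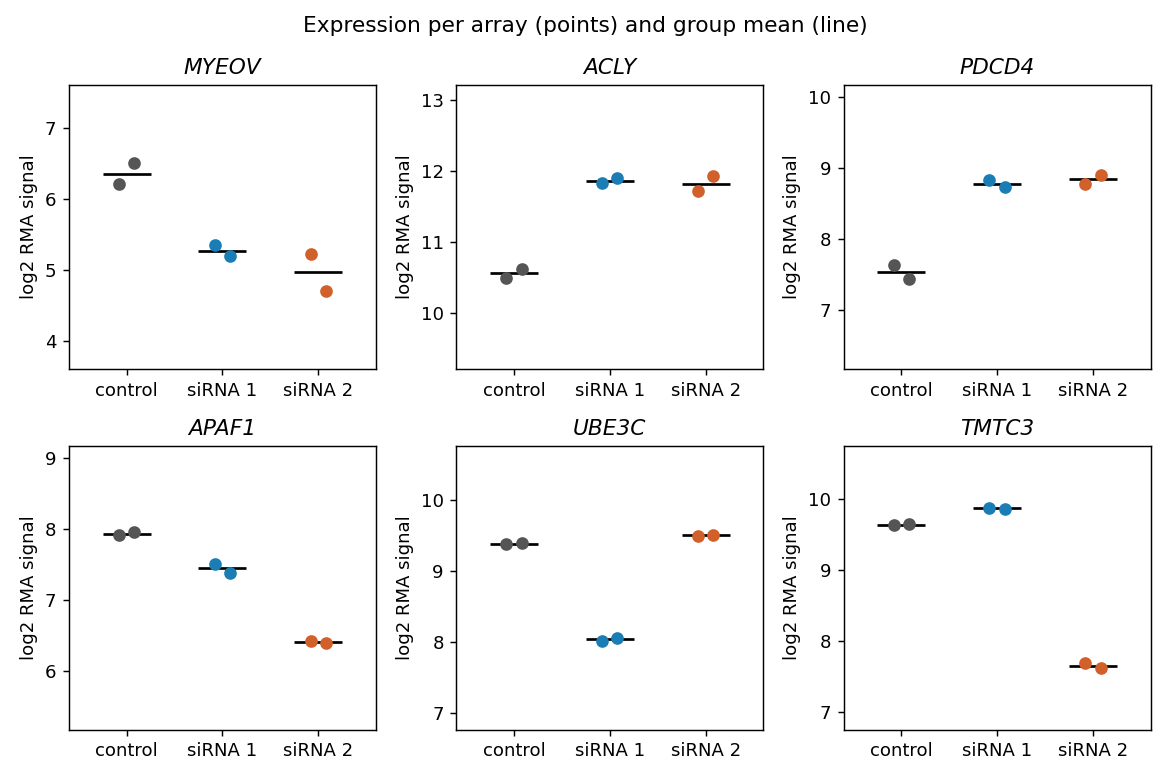
Log2 RMA signal of 6 genes in each array, with the points standing for single arrays and the lines for group means, each panel spanning the same number of log2 units. MYEOV and APAF1 were lower and ACLY and PDCD4 higher with both siRNAs, whereas UBE3C was lower with siRNA 1 and TMTC3 with siRNA 2.

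With siRNA 1, the largest rises were of ACLY, which makes cytosolic acetyl-CoA for lipid synthesis, by 1.31 ± 0.09 (SE), and PDCD4, an inhibitor of translation initiation, by 1.24 ± 0.09. TMEM87B, RASEF and TMEM65 rose by 1.23, 1.22 and 1.16, and the centromere factors MIS18A and CENPK by 1.13 and 0.97. The mitotic kinase NEK7 rose by 1.08, the membrane protein FLRT3 by 0.99 and TMEM64 by 0.97. The largest falls among ranked genes were of GPR180, at -1.43 ± 0.09, and the ubiquitin ligase UBE3C, at -1.35 ± 0.06. SKAP2, TEX30, the sphingosine-1-phosphate phosphatase SGPP1 and the deubiquitinase STAMBP had log2 fold changes of -1.20, -1.19, -1.17 and -1.12, and the kinase SLK, the metalloprotease ADAM9 and the Polycomb protein SCML2 of -1.10, -1.08 and -1.05.

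Among the 7442 genes tested, limma with Benjamini-Hochberg adjustment called 347 genes for siRNA 1, 170 higher and 177 lower. Of these, 8 were at least 2-fold higher and 14 at least 2-fold lower. At an unadjusted p under 0.05 there were 1430. The higher and lower calls numbered 188 and 161 with quantile normalization and 260 and 241 with the trend and robust prior. With no filter on dim genes 39 were called, with every row tested 187, and without control replicate 1, control replicate 2, siRNA 1 replicate 1 or siRNA 1 replicate 2 there were 93, 87, 97 and 58.

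The gene lists moved by small amounts with siRNA 1, and all 4 list calls in this paragraph were lost with an estimated correlation (camera adjusted p = 0.998 for each). That setting rests on the 3 residual degrees of freedom, so almost no list could pass it, and the loss cannot decide whether the calls hold. The estimated correlation was 0.431 for G1/S, -0.0885 for NRF2, 0.146 for ribosome biogenesis and 0.235 for fatty acid synthesis. For NRF2 it was below the preset 0.01, yet the unadjusted camera p rose from 0.000884 to 0.0407. For G1/S, ribosome biogenesis and fatty acid synthesis the unadjusted camera p rose further, from 0.000742, 0.00149 and 0.00441 to 0.333, 0.147 and 0.211. Their estimated correlations were above the preset, so these losses also reflect the correlation between members and not the degrees of freedom alone. G1/S and DNA replication genes were lower on average, at -0.13 over 23 tested members (camera adjusted p = 0.0208). Of these, 1 was called lower, the phosphatase CDC25A at -0.70, and 1 higher and 2 lower when adjusted over the list alone. NRF2 targets, antioxidant genes, averaged -0.19 over 9 members (adjusted p = 0.0208), with HMOX1, heme oxygenase, called at -0.49 and 2 lower when adjusted over the list alone. With siRNA 2, HMOX1 was called in the opposite direction, at 0.53, and the NRF2 list averaged 0.02 (camera adjusted p = 0.904), with 1 member called higher and 1 lower. Ribosome biogenesis and MYC targets averaged -0.13 over 15 members (adjusted p = 0.0209), with 0 members called by limma over all genes or adjusted over the list alone and 5 at an unadjusted p under 0.05. Fatty acid synthesis genes averaged 0.20 over 12 members (adjusted p = 0.0463), with ACLY and the elongase ELOVL5, at 0.35, called, also when adjusted over the list alone. Without ACLY, an alternative chosen after seeing the data, the fatty acid list averaged 0.10 (adjusted p = 0.206), and with the rows of a gene averaged it had adjusted p = 0.0846. The lowest adjusted p of camera over its alternatives was 0.000558, 0.0105, 0.0150 and 0.0254 in the order given. Without control replicate 1 the fatty acid list had adjusted p = 0.175, and without control replicate 2 the G1/S and ribosome biogenesis lists had 0.191 and 0.0560. Without siRNA 1 replicate 1 the G1/S, NRF2 and ribosome biogenesis lists had 0.305, 0.0549 and 0.0612, and without siRNA 1 replicate 2 the fatty acid list had 0.206.

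With siRNA 2, TMTC3, a transmembrane mannosyltransferase, fell by 1.99 ± 0.07 (SE) and the DNA helicase RECQL fell by 1.69 ± 0.09. ISOC1, ARHGAP1, the mRNA export factor ALYREF and PRUNE1 had log2 fold changes of -1.63, -1.61, -1.60 and -1.56. APAF1, the core of the apoptosome, had -1.53, ANKRD1 -1.50, BZW2 -1.46 and the splicing factor SMU1 -1.46. The kinase UHMK1 rose by 1.58 ± 0.08 and cyclin E2, CCNE2, by 1.08 ± 0.10. TMEM65, CENPK, PDCD4, TMEM87B, ACLY, NEK7, LBR and MIS18A rose by 1.44, 1.34, 1.30, 1.29, 1.27, 1.20, 1.14 and 1.11.

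For siRNA 2, limma with Benjamini-Hochberg adjustment called 508 genes, 193 higher and 315 lower, with 11 at least 2-fold higher and 31 at least 2-fold lower. At an unadjusted p under 0.05 there were 1649. With no filter 139 were called, with only the arrays of the 2 groups 331, and without control replicate 1, control replicate 2, siRNA 1 replicate 1, siRNA 1 replicate 2, siRNA 2 replicate 1 or siRNA 2 replicate 2 there were 211, 212, 331, 331, 217 and 207.

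YAP/TAZ targets, genes driven by the Hippo pathway's coactivators, were lower with siRNA 2, at -0.36 on average over 12 tested members (camera adjusted p = 0.00134). The call was lost with an estimated correlation (adjusted p = 0.998), a setting that almost no list could pass with 3 residual degrees of freedom. The list's estimated correlation was 0.0425, against the preset 0.01, and the unadjusted camera p rose from 1.6e-05 to 0.0330. ANKRD1, the matricellular protein CCN2, AJUBA and CRIM1 fell, at -1.50, -0.67, -0.53 and -0.45, and 5 members were lower when adjusted over the list alone. Without ANKRD1, chosen after seeing the data, the average was -0.26 (adjusted p = 0.0207). With siRNA 1 the list averaged -0.02 (adjusted p = 0.860), with 0 members called by limma. With siRNA 2, over its alternatives, the adjusted p of camera ran from 0.000389 to 0.998. Camera called fatty acid synthesis genes higher with siRNA 2 without siRNA 2 replicate 1 (adjusted p = 0.0364). G1/S and DNA replication genes were not called as a list with siRNA 2 (adjusted p = 0.101), but were called, as lower, with no filter (camera adjusted p = 0.0433), with the 75th percentile filter (0.0420) and without control replicate 1 or siRNA 2 replicate 2 (0.0287 and 0.0126). Of their members, cyclin D1, CCND1, at -0.72, the replication factor GINS1, at -0.48, and CCNE1, at -0.33, fell and CCNE2 rose. Adjusted over the list alone, 1 was higher and 4 lower.

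**Figure D2:**
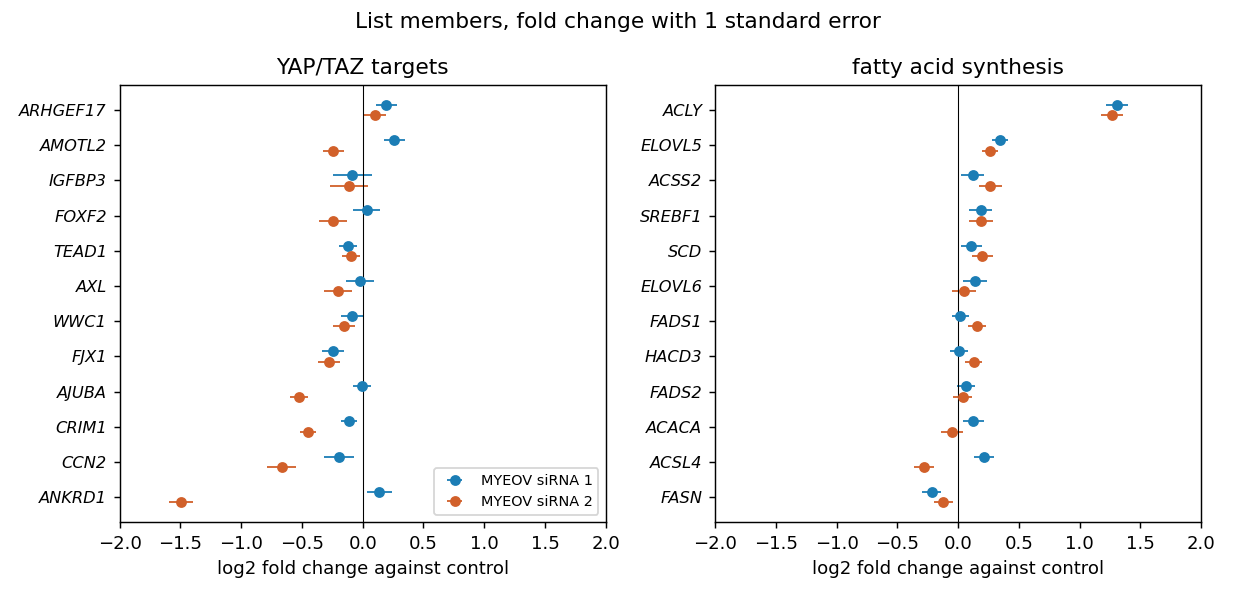
Log2 fold change against control of each tested member of the YAP/TAZ target and fatty acid synthesis lists, with points for siRNA 1 and siRNA 2 and bars for 1 standard error from limma. ANKRD1 at -1.50 with siRNA 2 and ACLY at 1.31 with siRNA 1 lie farthest from 0 in their lists.

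Most genes that changed in the same direction with both siRNAs rose. ACLY and PDCD4 rose by over 2-fold with each siRNA, as did TMEM87B, TMEM65, MIS18A and NEK7. RASEF and CENPK followed, by 0.99 and 0.97 with the siRNA that raised each less, then LBR, an inner nuclear membrane protein, by 0.93. CHMP4C, an ESCRT-III subunit, rose by 0.83 and 0.94 with siRNA 1 and siRNA 2, KLHL15 by 0.88 and 0.82, and the endosomal protein ANKFY1 by 0.85 and 0.82. After MYEOV, the shared falls were of RUFY2 (-0.72 and -0.53), the tRNA modification enzyme YRDC (-0.81 and -0.52), DDAH1 (-0.50 and -0.74), the ceramidase ACER2 (-0.64 and -0.50) and APAF1 (-0.49 and -1.53). SMIM15 (-0.40 and -0.60), the chromatin remodeller CHD7 (-0.40 and -0.42), ZBTB24 (-0.39 and -0.38), the phospholipase DDHD1 (-0.54 and -0.35), PURB (-0.35 and -0.47) and ISOC1 (-0.34 and -1.63) were also lower with both. With no filter, 0 of these 11 genes were called with siRNA 1. DDHD1 was not called when the rows of a gene were averaged (limma, Benjamini-Hochberg adjusted p = 0.195 and 0.344 for siRNA 1 and siRNA 2, the highest of all alternatives, where the lowest were 0.00115 and 0.00606).

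Both siRNAs called 91 genes in the same direction, 75 higher and 16 lower, and 11 in opposite directions. Independent lists of these sizes would share 4.41 higher, 7.49 lower and 11.8 opposite genes. Unchanged groups simulated against the shared controls gave 0.01 shared calls on average, and taking as many top genes from them as were called gave 33.7 higher and 46.6 lower. The correlation of the fold changes across genes, which are not independent replicates, was 0.361, against 0.497 simulated with no effect. Their covariance was 0.0161 against 0.00684, a difference of 0.00926. The same sign was seen for 63.9% of genes against 66.7% simulated. The simulations hold no effect of either siRNA, and effects of a single siRNA can lower the correlation, the share of one sign and the overlap. Values below the simulated ones therefore do not show that the siRNAs agreed less than unchanged groups would. Part of the excess over independent lists, and of the covariance, may come from the shared controls. With each siRNA set against a different control array, a test chosen after the results were seen, the correlation was 0.179 and 0.170 in the 2 assignments, and 0 and 3 genes were called lower in both, against 1.54 and 1.81 from independent lists. With no filter, 11 genes were called by both, all higher, and without control replicate 1, control replicate 2, siRNA 1 replicate 1, siRNA 1 replicate 2, siRNA 2 replicate 1 or siRNA 2 replicate 2 there were 25, 25, 24, 16, 41 and 39. In the same order of arrays left out, the genes lower with both numbered 0, 1, 2, 0, 5 and 6, and the 1 without control replicate 2 was not among the 16. With every row tested there were 51, with the 75th percentile filter 143 and with the trend and robust prior 156.

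**Figure D3:**
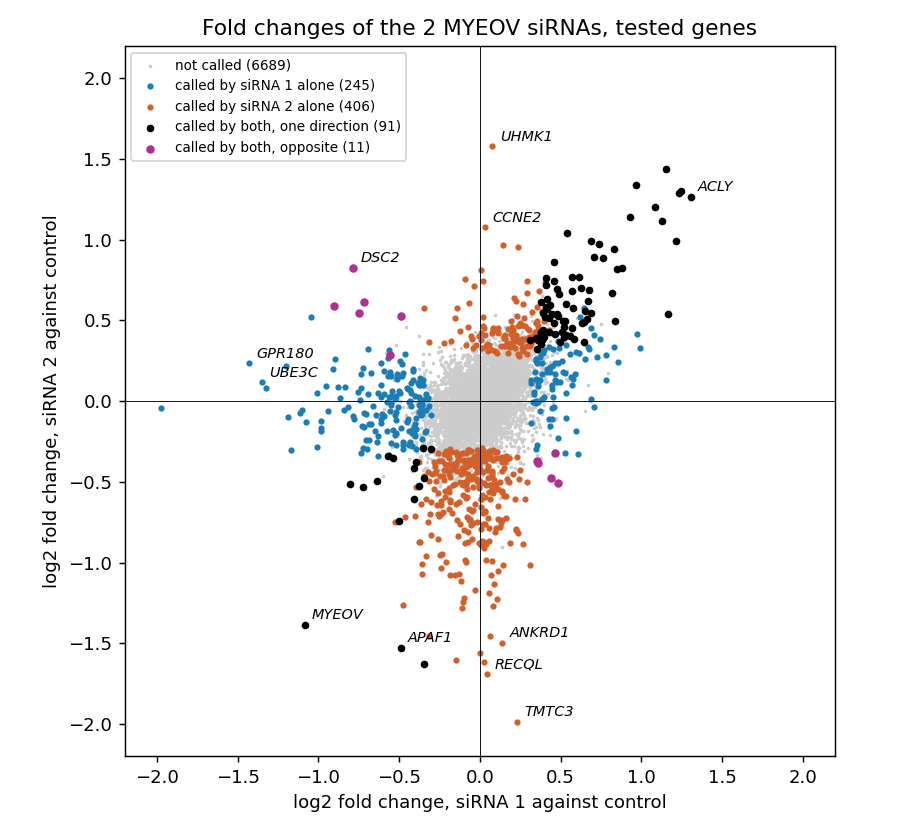
Log2 fold change of each tested gene with siRNA 1 (horizontal) and siRNA 2 (vertical) against the same control arrays, coloured by which siRNA called it. The 75 genes called higher by both lie at upper right, and the genes farthest from 0 for 1 siRNA, such as TMTC3 and UBE3C, lie near an axis.

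For the mean of both siRNAs, ACLY rose by 1.29 and the fall of APAF1 averaged -1.01. Limma with Benjamini-Hochberg adjustment called 403 genes, 190 higher and 213 lower, with 9 and 3 of them at least 2-fold. Genes called with 1 siRNA alone were among them. Examples are TMTC3, at 0.23 with siRNA 1 and -1.99 with siRNA 2 (adjusted p for the mean = 0.00102), and UBE3C, at -1.35 and 0.12 (0.00319). More were higher than lower with quantile normalization (217 and 197), with no filter (16 and 10) and without control replicate 1 (37 and 31) or control replicate 2 (48 and 33). With no filter 26 were called, with every row tested 255, and without the arrays of control, siRNA 1 and siRNA 2 in turn, replicate 1 before replicate 2, there were 68, 81, 201, 160, 239 and 216. As lists, G1/S and DNA replication genes averaged -0.12 (camera adjusted p = 0.0208), YAP/TAZ targets -0.19 (adjusted p = 0.0208) and fatty acid synthesis genes 0.19 (adjusted p = 0.0368). All 3 calls were lost with an estimated correlation (adjusted p = 0.998 for each), which almost no list could pass with 3 residual degrees of freedom. The unadjusted camera p with that setting was 0.342 for G1/S, 0.0672 for YAP/TAZ and 0.198 for fatty acid synthesis. The YAP/TAZ fall was that of siRNA 2, as siRNA 1 averaged -0.02. The first had 1 higher and 2 lower members, the second 2 lower and the third 2 higher, and adjusted over the list alone 2 higher and 5 lower, 5 lower and 2 higher. Ribosome biogenesis and MYC targets were not called for the mean, but were called, as lower, with no filter (adjusted p = 0.0295), with the replicate block (0.0496) and without siRNA 2 replicate 1. For the 3 called lists, the lowest adjusted p of camera over its alternatives was 0.00179, 0.00943 and 0.0170. Without ANKRD1 and without ACLY the YAP/TAZ and fatty acid lists had adjusted p = 0.0697 and 0.179, and with the rows of a gene averaged the fatty acid list had 0.0723. The G1/S call was lost without control replicate 2, siRNA 1 replicate 1 or siRNA 2 replicate 1 (adjusted p = 0.191, 0.0938 and 0.0741), the YAP/TAZ call without siRNA 1 replicate 1 (0.0524), and the fatty acid call without control replicate 1, siRNA 1 replicate 2 or siRNA 2 replicate 2 (0.159, 0.0892 and 0.115).

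Of the 28 lists tested, 23 were not called by camera in any of the 3 contrasts, but camera called 6 of these under some alternative and fry, in either direction, called 14 and, in a single direction, 0. Fry in either direction asks whether any members of a list changed, whereas camera asks whether a list moved in one direction relative to other genes. Its 14 calls are therefore not shifts that camera missed. With no filter, RNA interference machinery was called lower and cholesterol and sterol synthesis higher with siRNA 2 (camera adjusted p = 0.0433 for each), and the 75th percentile filter called cholesterol synthesis and, as lower, Wnt targets with siRNA 2 (0.0337 for each). Without siRNA 2 replicate 1 cholesterol synthesis had 0.0449. ERK output genes were called lower with siRNA 1, siRNA 2 and their mean without control replicate 2 (0.00870, 0.0104 and 0.00336), with siRNA 1 and the mean without siRNA 1 replicate 1 (0.0354 for each), and with siRNA 2 and the mean without siRNA 2 replicate 1 (0.0170 and 0.0194). G2/M and mitosis genes were called lower with siRNA 1 and for the mean without control replicate 1 (0.00226 and 0.00356) and with siRNA 1 without siRNA 1 replicate 2 (0.0228), and NF-kB and inflammatory cytokines higher without siRNA 1 replicate 2 (0.0447). The replicate block called ERK output genes lower with siRNA 1 and for the mean (camera adjusted p = 0.0239 and 0.0306). These calls used the preset correlation of 0.01, whereas the estimated correlation was 0.600 for ERK output and 0.590 for G2/M and mitosis. With it and all arrays, the unadjusted camera p of ERK output was 0.544, 0.558 and 0.502 for siRNA 1, siRNA 2 and their mean. With all arrays, the filter and no block, ERK output genes had a smallest adjusted p of 0.129, and the feedback inhibitor SPRY2 fell with siRNA 2, at -0.60. Cholesterol and sterol synthesis genes had 0.0851, with INSIG1 higher with siRNA 2, at 0.39, and IDI1 and STARD4 lower with siRNA 1, at -0.55 and -0.51. RNA interference machinery had 0.101, NF-kB and inflammatory cytokines 0.14, apoptosis regulators 0.152 and G2/M and mitosis 0.205. Genes that neighbour MYEOV on its chromosome arm had 0.314, with CCND1 lower with siRNA 2. The smallest adjusted p was 0.401 for epithelial junctions and keratins, 0.436 for Wnt targets, 0.481 for TGF-beta targets, 0.481 for hypoxia and glycolysis and 0.499 for integrins and adhesion. It was 0.687 for each of mesenchymal state, type I interferon response, unfolded protein response, oxidative phosphorylation and ribosomal proteins. It was 0.848 for matrix proteases, lysosome and autophagy, and alveolar and airway secretory markers, 0.856 for p53 targets, 0.873 for the amino acid response and 0.887 for the EGFR and ERBB family. With no filter, limma called 1 of 12 p53 targets higher with siRNA 1, with siRNA 2 and for their mean. The list itself was still not called by camera (adjusted p = 0.902, 0.516 and 0.678). Blood cell, endothelial, and squamous and neuroendocrine markers had 1, 1 and 2 tested members, of which 0 were called by limma with either siRNA and, at an unadjusted p under 0.05, 1 blood cell marker with siRNA 1 and 1 squamous or neuroendocrine marker with each siRNA. Fibroblast markers had 0 tested.

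The siRNAs differed from each other in more genes than either differed from control, except without siRNA 1 replicate 1 or siRNA 1 replicate 2, where 280 and 226 genes differed between them and 331 with siRNA 2 against control. TMTC3 was higher with siRNA 1 than with siRNA 2 by 2.22, RECQL by 1.74, ARHGAP1 by 1.64, ANKRD1 by 1.63, PRUNE1 by 1.56 and SMU1 by 1.52. GPR180 was lower with siRNA 1 than with siRNA 2, at -1.66, as were the desmosomal cadherin DSC2 at -1.61, SCML2 at -1.57, UHMK1 at -1.50, the glycosyltransferase GALNT1 at -1.49 and UBE3C at -1.46. DSC2 and GALNT1 fell with siRNA 1, at -0.78 and -0.90, and rose with siRNA 2, by 0.83 and 0.59. Limma with Benjamini-Hochberg adjustment called 681 genes between the siRNAs, 400 higher and 281 lower with siRNA 1, with 30 and 21 of them at least 2-fold. At an unadjusted p under 0.05 there were 1756. With no filter 195 were called, and without siRNA 1 replicate 1, siRNA 1 replicate 2, siRNA 2 replicate 1 or siRNA 2 replicate 2 there were 280, 226, 318 and 317.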

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

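The tests weighing explanations and the list tests between the siRNAs were chosen after the results were seen. Each value in the first paragraph is siRNA 1 minus siRNA 2 on the log2 scale, singled out because limma (for lists, camera) called the difference between the siRNAs. Among genes lower with siRNA 1 than siRNA 2, the differences were MIR31HG -1.94, GPR180 -1.66, DSC2 -1.61, SCML2 -1.57, UHMK1 -1.50, GALNT1 -1.49, UBE3C -1.46, SKAP2 -1.41, C5orf15 -1.40, SCML1 -1.29, SUZ12 -1.16, TEX30 -1.09, CCNE2 -1.04, SLK -1.04, STAMBP -1.04, HMOX1 -1.02, ADAM9 -0.95, SGPP1 -0.87, PCGF5 -0.82, IDI1 -0.74, STARD4 -0.47, CDC25A -0.40, IRF9 -0.38, CENPK -0.37 and EZH2 -0.37. Among genes higher with siRNA 1, they were TMTC3 2.22, RECQL 1.74, ARHGAP1 1.64, ANKRD1 1.63, PRUNE1 1.56, SMU1 1.52, ALYREF 1.45, ISOC1 1.29, BZW2 1.15, APAF1 1.04, DKK1 0.94, CENPA 0.70, FLRT3 0.66, CCND1 0.64, DDX60 0.58, TMEM64 0.56, AJUBA 0.52, GINS1 0.46, CRIM1 0.34 and UGDH 0.33. MIR31HG, C5orf15, SCML1, SUZ12, PCGF5, EZH2 and CENPA were chosen after their values were seen. As lists, YAP/TAZ targets differed by 0.344 (camera, limma, Benjamini-Hochberg adjusted p = 0.00492 over 28 tests), NF-kB and inflammatory cytokines by 0.294 (adjusted p = 0.0179), Wnt targets by 0.287 (adjusted p = 0.0179) and NRF2 targets by -0.215 (adjusted p = 0.0417). With an estimated correlation these 4 adjusted p were 0.710, 0.759, 0.710 and 0.710, but almost no list could pass that setting with 3 residual degrees of freedom.

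Genes called by both siRNAs mostly rose, 75 of 91. Chance error of each control array on its own is argued against: with each siRNA set against a different control array, and the spread taken from all groups, 27 and 24 genes were called higher in both, at least 40.9 times the number from independent lists, though for the genes lower in both, 0 and 3 against 1.54 and 1.81, it stays open, as does an error common to both control arrays, such as that of a single transfection. Off-target lowering of transcripts by the control siRNA, which would appear as a rise with both MYEOV siRNAs, stays open, as a hypothesis. The share that rose, 82.4% of genes called by both against 31.0% of the 651 called by 1 siRNA, restates the pattern and does not bear on its cause. Loss of MYEOV cannot be told apart from this, since it also predicts like rises with both (median difference between the siRNAs -0.044, median rise 0.57), and no untransfected or second control was analysed here.

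Most genes changed at least 2-fold by a single siRNA were lower. A fall in proportion to a deeper lowering of MYEOV by siRNA 2 is argued against. Besides MYEOV, 30 genes were at least 2-fold lower with siRNA 2. Their median ratio of siRNA 1 to siRNA 2 fold changes was 0.0534 (quartiles -0.0651 and 0.165). For MYEOV it was 0.783, from changes that did not differ detectably between the siRNAs. Picking genes by their fall with siRNA 2 draws the ratio down, and falls not in proportion to MYEOV were not tested. Off-target lowering by each MYEOV siRNA stays open, as a hypothesis. Of genes called by 1 siRNA, 95.3% of those changed at least 2-fold were lower (41 of 43) and 67.1% of those changed less, which restates the pattern. The siRNA sequences were not analysed here, so seed matches in these transcripts stay untested.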

How the results depend on the processing

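The lists without ACLY or ANKRD1 and camera on the difference between the siRNAs were chosen after seeing the data, the other alternatives before. Named genes were followed in the contrasts where they were ranked or called, and lists where they were called. There, no fold change or list average changed sign. Elsewhere signs could change, as for YAP/TAZ targets with siRNA 1, at -0.02 with the filter and 0.01 with no filter. The main calls for siRNA 1 were near even, 170 higher and 177 lower. Higher calls outnumbered lower ones with quantile normalization (188 and 161), the replicate block (213 and 207) and the trend and robust prior (260 and 241). For the mean they did so with quantile normalization (217 and 197), no filter (16 and 10) and without either control array. With no filter, calls fell to 39 for siRNA 1, 139 for siRNA 2, 26 for their mean, 195 between the siRNAs and 11 shared, the correlation was 0.424 and the covariance 0.0194, and MYEOV with siRNA 1, still at -1.09, missed the threshold. More tests of dim genes enter that adjustment, and the spread that limma shares between genes was estimated again with the dim genes included. The 2 effects were not tested apart. At the 75th percentile there were 143 shared calls, a correlation of 0.315 and a covariance of 0.0148, and MYEOV was below the filter. Every row gave 187 calls for siRNA 1, 255 for the mean and 51 shared, the arrays of 2 groups alone 331 for siRNA 2, and the trend and robust prior 156 shared, and the cause was not tested. Of 84 list tests camera called 8, and 0 with an estimated correlation (2 at an unadjusted p under 0.05), fry called 0 in a single direction (22 unadjusted) and 47 in either. Camera with an estimated correlation rests on the 3 residual degrees of freedom, so almost no list could pass it and it cannot decide whether the calls hold. Leaving out single arrays, a lone array being assumed to vary like the other groups, gave 58 to 235 calls for siRNA 1, 207 to 331 for siRNA 2, 68 to 239 for the mean, 226 to 618 between the siRNAs, 16 to 41 shared and 5 to 12 list calls, with 5 without siRNA 1 replicate 1. The correlation ran from 0.312 to 0.462, the covariance from 0.0145 to 0.0245, and MYEOV from -1.23 to -0.94 with siRNA 1 and from -1.65 to -1.13 with siRNA 2. Of calls of ranked genes, 33 were lost over the other alternatives and 650 held, and 87 were lost and 387 held without single arrays. For other named genes 48 were lost and 373 held, and 118 and 170 without single arrays. Same-numbered replicates correlated at 0.265, 0.205 and 0.251. The labels tie them by number alone, so whether they were paired stays open. The replicate block gave 420, 702, 531 and 922 calls for siRNA 1, siRNA 2, their mean and the difference, with 133 shared and 11 list calls, among them ERK output genes with siRNA 1 and for the mean (camera adjusted p = 0.0239 and 0.0306) and ribosome biogenesis and MYC targets for the mean (0.0496), not called without it.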

Other observations

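Both tests in the second paragraph were chosen after the results were seen. Genes of the type I interferon response, which siRNA can induce, averaged 0.01 with siRNA 1 and -0.02 with siRNA 2 on the log2 scale over 23 genes with no filter, most of them dim, with a median control level of 4.31. Camera's adjusted p was 0.883, 0.754 and 0.993 for siRNA 1, siRNA 2 and their mean. The control cells also received an siRNA, so a response common to all siRNAs would not show in these values. With the filter, IRF9 rose, at 0.41, and DDX60 fell, at -0.35, with siRNA 2. MIR31HG, a long non-coding RNA chosen after its values were seen, had the largest fall with siRNA 1, at -1.98 ± 0.09 (SE, n = 2), and -0.04 with siRNA 2. Among the 8516 unnamed rows at the tested level, limma with Benjamini-Hochberg adjustment called 39 higher and 47 lower with siRNA 1 and 43 higher and 96 lower with siRNA 2.

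Among the genes lowered by siRNA 1 were the Polycomb repressor subunits SUZ12, at -0.90, PCGF5, at -0.98, L3MBTL2, at -0.63, SCML2, at -1.05, SCML1, at -0.75, and EZH2, at -0.37. All but SCML2, which the ranking named, were chosen after their values were seen. With siRNA 2, SCML1 was higher, at 0.54, SCML2, at 0.52, was not called (limma, Benjamini-Hochberg adjusted p = 0.0761), and the Polycomb list had an adjusted p = 0.955, with 2 members called higher and 1 lower. A shift of the whole Polycomb group with siRNA 1 is a hypothesis that stays open. Camera from limma on 33 tested members gave a Benjamini-Hochberg adjusted p = 0.0412 over 8 tests of both groups (0.00515 before adjustment), and adjusted p = 0.286 with an estimated correlation (0.0493 before), but 27 were not called and the median was -0.04. A requirement that the median reach 0.1 in size was added after these p-values were seen, and without it the list would have met its test. The test also ran on a list drawn up because some members had fallen, so it is not independent evidence. Whether the rises of CENPK, MIS18A and CENPQ belong to a shift of the whole centromere complex, of which 18 members were tested, also stays open, and CENPA, another member, fell with siRNA 2, at -0.56 (limma, Benjamini-Hochberg adjusted p = 0.0187). For the mean of both siRNAs camera gave an adjusted p = 0.157 (0.0978 before adjustment), with an average of 0.15, a median of 0.03 and 15 members not called. With siRNA 2 the adjusted p was 0.0928 (0.0390 before adjustment), with 3 members called higher and 1 lower. A camera p of 0.05 or more first counted against this shift, and that rule was dropped after the results were seen.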
